A study of Mus musculus with 8 samples.

How the data were processed

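RNA was measured in muscle stem cells isolated by fluorescence-activated sorting from the hindlimb muscles of wild-type C57BL/6 mice, 4 libraries from young mice (3 months) and 4 from old mice (20 months). Per the labels, libraries were made with a Nextera XT kit from amplified cDNA, whose reads carry no molecular identifiers. The submitters' processing notes name Trim Galore 0.4.2, STAR, Subread 1.5.1 with featureCounts, and DESeq2. They name the builds GRCm39 and mm10 without saying which was used for what, and the file gives gene symbols only, so that no coordinates are printed. The labels do not state the strandedness of the libraries, so reads from genes that overlap on opposite strands may not be separable, and reads of near-identical genes such as Amd1 and Amd2, histones, ribosomal proteins and haemoglobins may be shared.

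The deposited signal of each gene is a normalized count, a whole number of reads divided by a size factor for the library. The smallest step of each column gave the value of 1 read, between 0.60 and 1.07 normalized counts, and dividing by it returned whole reads (within 0.01 reads) for at least 99.98% of the values above 0. The file held 31723 genes, of which 14822 with a mean of at least 10 normalized counts over the 8 libraries were tested. The recovered reads came to between 19.04 and 34.68 M reads per library, and they measure depth as assigned to genes, since the number of sequenced reads is not in the file. The 13 mitochondrially encoded genes of the file were listed at 0 in every library.

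The test was limma 3.58.1 (R 4.3.3), with an intensity trend in the variance, on log2(normalized count + 1), with age as the only term, two-sided, and with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 52 of the 54 fixed lists with at least 5 tested members. The list of mitochondrially encoded transcripts had 0 tested members and that of sex-linked genes had 4. Each list was also tested with an estimated correlation, under which none of the 15 called lists passed, and with fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. Fry called 2 lists higher (senescence secretory factors and glutathione and NRF2 targets) and 2 lower (folate cycle and serine synthesis, and the unfolded protein and integrated stress response). Exact permutation tests over the 70 arrangements of 4 and 4 libraries compared mean log2 levels of lists, and the smallest p they can give is 0.0286. Within-age correlations are single values over all libraries, taken after the mean of each age was subtracted. They need not hold in each age alone.

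The grouping, the test, the filter, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made later. The rule named the 12 genes with the highest and the 12 with the lowest log2 fold change among called genes with a mean of at least 50 normalized counts whose libraries separated fully by age, leaving out predicted models and pseudogenes. It also named every member of the SAM and polyamine lists that passed over all genes or over the list alone, up to 4 members with the smallest p of each other list, and fixed genes of the study question and of cell identity. The rule gave 240 genes, not all of which are described. Named after their values were seen were Kdm1a, Kdm5c, Mirg, Grb10, Sgce, Sdc2, Atf4, Ddit3, Xbp1, Fmod, Col3a1, Col4a1, Lamc1, Sparc, Smad5, Gpi1, Gstm1, Actb, Actg1, Gpnmb, Eya2, Bicd1, Nars, Yars, Lars, Cyp51, Msmo1, Hmgcs1, Arntl, Npas2, Per1, Per3, Nr1d1, Nr1d2, Dbp and Tef.

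Alternatives fixed in advance were pseudocounts of 0.5 and 8, no filter and a minimum mean of 50, quantile normalization, equal library totals, eBayes without the trend, sample weights, the replicate number as a block, leaving out each library in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Added after the data were seen were the mean log2 level of fibroblast and tenocyte markers as a covariate, that of endothelial markers as a covariate, and leaving out young library 3 and old library 3. GC content and transcript length for 14552 of the tested genes came from a mouse reference annotation.

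The test was tried on simulated data made from these libraries, with changes put into 200 of 14822 genes, a shift put into a list of 35 further genes, and the comparison of 4 against 4. Limma recovered 13 of 67 genes changed 1.5-fold (19.4%), 45 of 67 changed 2-fold (67.2%) and 64 of 66 changed 4-fold (97.0%), and called 5 of 14587 unchanged genes and 0 of 51 unchanged lists. In these simulated data most changes of 1.5-fold were missed. The simulated genes were drawn independently of each other. The 0 of 51 therefore does not test lists whose genes vary together, as in the real data (estimated correlation 0.606 for ribosomal proteins and 0.481 for fibro-adipogenic progenitor markers).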

Results

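RNA was sequenced from muscle stem cells, the Pax7-expressing progenitors that lie beside the fibres of skeletal muscle, sorted by flow cytometry from the hindlimb muscles of wild-type C57BL/6 mice. There were 8 libraries, 4 from young mice (3 months) and 4 from old mice (20 months), all made from freshly isolated cells. The labels list the libraries as separate samples and do not say whether each came from 1 animal or a pool, so that every p-value measures the spread between these samples. The libraries held between 19.04 and 34.68 M recovered reads assigned to genes, with 27.8 ± 5.69 M (SD, n = 4) in young and 23.5 ± 3.51 M (n = 4) in old (exact permutation p = 0.286, two-sided). Between 18428 and 19013 genes had a value above 0 in a library. The series asks how ageing of these cells relates to S-adenosylmethionine (SAM), the methyl donor of the cell, and to heterochromatin, and the design implies a single comparison, old against young. Changes are given as log2 fold changes (old over young) ± SE on the log2(normalized count + 1) scale, which understates the change of low genes, and levels as mean normalized count ± SD over the 4 libraries of an age.

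In old cells 495 genes were higher and 278 were lower among 14822 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 260 of the higher and 46 of the lower genes differed at least 2-fold. Among called genes with a mean count of at least 50 that separated all young from all old libraries, the largest increase was that of Spock1. This proteoglycan gene rose from low counts (22.7 ± 20.2 in young, 423 ± 147 in old, log2 fold change 4.39 ± 0.48, adjusted p = 0.00161). Col4a6 and Col4a5, which encode chains of basement membrane collagen, rose by 4.29 ± 0.24 (adjusted p = 6.75e-05) and 2.78 ± 0.28 (adjusted p = 9.13e-04), the first from 20.5 ± 6.46 to 409.9 ± 59.7 normalized counts. Cyp26a1, a retinoic acid-degrading enzyme, rose from 485 ± 276 to 4917 ± 2212 (log2 fold change 3.40 ± 0.37, adjusted p = 0.00152). Among the largest decreases were the calcium channel subunit Cacna2d4 (-3.00 ± 0.44, adjusted p = 0.00562), the diacylglycerol kinase Dgkg (-2.14 ± 0.18, adjusted p = 5.62e-04) and the tubulin gene Tubb4a (-1.85 ± 0.16, adjusted p = 5.62e-04).

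The 12 highest genes by this rule also held Slc27a2, a fatty acid transporter and acyl-CoA synthetase (3.78), the matrix protease Mmp3 (3.68), the secreted factor Ccbe1 (3.75) and the tachykinin gene Tac1 (3.42). The others were the synaptic vesicle gene Sv2b (3.34), the carboxylesterase Ces1d (3.17), and the matrix-associated genes Angptl7 (3.43), Edil3 (3.10) and Cilp (3.09). The 12 lowest also held another tachykinin gene, Tac4 (-2.38), the intestinal-type glucosidase Mgam (-2.04), Sln, the sarcolipin that regulates the muscle calcium pump (-2.01), and the adrenergic receptor Adra1b (-1.99). The others were the transcription factor Sox11 (-1.91), Ret, the receptor for the GDNF family (-1.61), Kcnab2 (-1.53), Scml4 (-1.47) and the death receptor Tnfrsf21 (-1.44, from 7267 ± 952 to 2747 ± 748). The count of higher genes went to 248 without young library 1, 246 without young library 4, 256 without old library 1, 213 without old library 2 and 229 without old library 4. That of lower genes went to 117, 127, 164, 150 and 136 in the same order. The genes at least 2-fold higher were then 166, 158, 161, 130 and 137. Of the 142 called genes named here, 81 kept the call without each library in turn and all kept their sign. The number that kept it was 91, 114, 129 and 90 without young libraries 1 to 4 and 100, 93, 125 and 96 without old libraries 1 to 4. Of all of them 12 lost their call in most of 23 alternatives: Hspa5 in 15, G6pdx, Grb10 and Rpl37a in 14, Ccbe1 and Kdm4b in 13, and Gpi1, H3c7, Ier3, Jmjd1c, Rrm2 and Slc16a1 in 12. Ccbe1 had 14.6 ± 21.7 normalized counts in young, with 46.5 in young library 2, and of the 8 runs without a library it kept its call in 1, that without young library 2. In a model that held the mean log2 level of fibroblast and tenocyte markers of each library as a covariate, chosen after the data were seen, 7 genes were higher and 3 lower. Over the 773 genes the median size of the change went from 0.83 to 0.67 and the median SE from 0.16 to 0.24, and all 773 kept their sign. Of the 12 highest genes, Angptl7 was then at 0.65, Cilp at 1.01, Edil3 at 1.20, Ces1d at 1.25, Tac1 at 1.26, Ccbe1 at 1.43, Mmp3 at 1.64 and Sv2b at 2.51. The within-age correlation of these 8 with the level of fibro-adipogenic progenitor markers was 0.487 (Sv2b) to 0.896 (Cilp). Cyp26a1 was at 3.15, Slc27a2 at 3.95, Col4a6 at 4.44 and Spock1 at 4.76, and of the 12 only Col4a6 passed (adjusted p = 0.0158).

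Of the enzymes that make and use SAM, few passed the test. Of 18 tested genes of the methionine cycle and SAM synthesis, 1 rose and 1 fell. Inmt, an indole and thioether methyltransferase that consumes SAM, rose from 222 ± 193 to 1163 ± 561 (log2 fold change 2.58 ± 0.50, adjusted p = 0.0179). It had a within-age correlation of 0.894 with the level of fibro-adipogenic progenitor markers, and with the fibroblast marker covariate it was at 0.76 (adjusted p = 0.594). It lost its call in 6 of 23 alternatives. Nnmt, the nicotinamide methyltransferase, another consumer of SAM, fell from 2872 ± 681 to 1541 ± 279 (-0.88 ± 0.18, adjusted p = 0.0227). Nnmt also lost its call in 6 of 23 alternatives, and with the fibroblast marker covariate it was at -0.68 (adjusted p = 0.517). Mat2a, which encodes the SAM synthetase of non-hepatic cells, was among the abundant transcripts at both ages, 62336 ± 7155 in young and 59366 ± 12848 in old, and did not pass the test (-0.090 ± 0.16, adjusted p = 0.809). Adjusted over the list alone, 5 genes passed, and the further 3 were all lower in old. They were Ahcy, which clears S-adenosylhomocysteine (-0.45 ± 0.14), the methionine synthase Mtr (-0.48 ± 0.13) and the amino acid transporter subunit Slc7a5 (-0.55 ± 0.15). Their adjusted p over all genes was 0.0938, 0.0604 and 0.0582. The list itself was not called (camera adjusted p = 0.379), its median change being 0.014 and its mean 0.063 while the test statistic pointed down. Under quantile normalization that median was -0.10.

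Polyamine synthesis consumes decarboxylated SAM, and of 20 tested genes of polyamine metabolism 1 rose and none fell, the same count as adjusted over the list alone. That gene was Azin2, an antizyme inhibitor that relieves the block on ornithine decarboxylase (151 ± 30.0 to 325 ± 37.9, log2 fold change 1.12 ± 0.17, adjusted p = 0.00662). The decarboxylases themselves did not pass the test. Odc1 had 61146 ± 7195 normalized counts in young and 57348 ± 8265 in old (-0.096 ± 0.13, adjusted p = 0.731). Amd1, which makes decarboxylated SAM and has a near-identical copy, Amd2, was at -0.17 ± 0.11 (adjusted p = 0.426). The aminopropyl transferases were Srm at -0.37 ± 0.15 (adjusted p = 0.20) and Sms at -0.39 ± 0.13 (adjusted p = 0.104), and the catabolic genes Sat1 and Smox were at -0.024 ± 0.080 and -0.071 ± 0.15. The median of the list was -0.048 (mean 0.011, camera adjusted p = 0.379, test statistic pointing down), and 0.020 without old library 3. Of 7 genes of the salvage route from methylthioadenosine, the by-product of polyamine synthesis, Mtap rose (0.68 ± 0.16, adjusted p = 0.0342), also over the list alone. Mtap lost its call in 8 of 23 alternatives, and the list was not called (median 0.16, adjusted p = 0.423).

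Some enzymes of serine synthesis and of the folate cycle, which supplies methyl groups to the methionine cycle, fell in old cells. Of 18 genes of the folate cycle and serine synthesis, 3 fell and none rose. They were the mitochondrial folate enzyme Mthfd2 (1690.4 ± 144 to 765 ± 72.4, log2 fold change -1.14 ± 0.10, adjusted p = 5.62e-04), the cytosolic serine hydroxymethyltransferase Shmt1 (-0.84 ± 0.16, adjusted p = 0.0146) and the serine synthesis enzyme Psat1 (-0.70 ± 0.15, adjusted p = 0.0276). Adjusted over the list alone, Phgdh, the first enzyme of serine synthesis, was a further lower gene (-0.59 ± 0.16, adjusted p over all genes = 0.0616). The list was not called by camera (adjusted p = 0.169), its median being 0.037 and its mean -0.066, with the test statistic pointing down. The median was -0.047 under quantile normalization and -0.0024 with DESeq2.

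**Figure D1:**
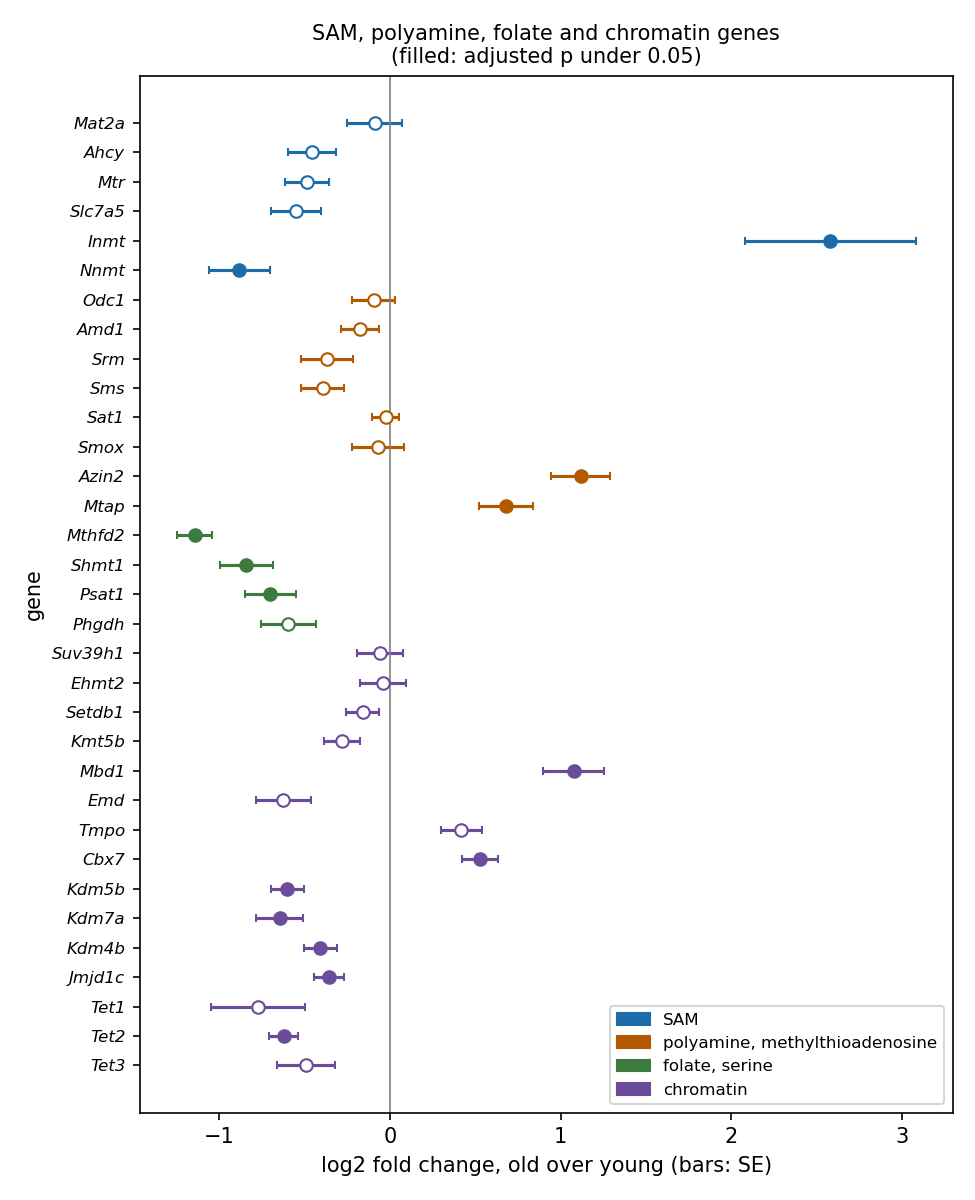
Log2 fold change (old over young, x axis) with its SE for the genes of SAM, polyamine, folate and chromatin enzymes named in the text, filled where the adjusted p over all genes was under 0.05. Inmt, Azin2, Mtap, Mbd1 and Cbx7 lay to the right and Mthfd2, Nnmt, Shmt1, Psat1, Kdm5b, Kdm7a, Kdm4b, Jmjd1c and Tet2 to the left, while Mat2a at -0.090 and Odc1 at -0.096 were open.

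The enzymes that write heterochromatin marks did not pass the test. None of 13 tested histone H3K9 and H4K20 methyltransferases passed the limma test over all genes or adjusted over the list alone. Among them were Suv39h1 (-0.056 ± 0.14), Ehmt2 (-0.038 ± 0.14), Setdb1 (-0.16 ± 0.097) and Kmt5b (-0.28 ± 0.10, adjusted p = 0.155, the lowest of the list). At an unadjusted p under 0.05, Kmt5b alone was lower, and edgeR and DESeq2 on the recovered reads called 0 and 0 of the 13. Of 22 heterochromatin proteins, 1 was called: Mbd1, a methyl-CpG binding protein, rose from 1288 ± 309 to 2697 ± 533 (1.08 ± 0.18, adjusted p = 0.0090). Adjusted over the list alone, Emd, the nuclear envelope protein emerin (-0.62 ± 0.16), and Tmpo, a lamina-associated protein (0.42 ± 0.12), also passed, in opposite directions. The medians of both lists lay near 0, -0.038 (mean 0.049, camera adjusted p = 0.722) and -0.0046 (mean 0.042, adjusted p = 0.886), with the test statistic of each pointing down. Without young library 3 the first median was 0.039, without old library 1 0.022 and without old library 4 0.034.

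Some enzymes that remove methyl marks fell. Of 21 histone demethylases 4 fell and none rose. They were Kdm5b, an H3K4 demethylase (2101 ± 203 to 1384 ± 108, -0.60 ± 0.098, adjusted p = 0.00875), Kdm7a (-0.64 ± 0.14), Kdm4b, an H3K9 demethylase (-0.41 ± 0.097), and Jmjd1c (-0.36 ± 0.086). Kdm4b lost its call in 13 of 23 alternatives and Jmjd1c in 12. Adjusted over the list alone 6 were lower, with Kdm1a and Kdm5c, named after their values were seen, at -0.32 and -0.34. The list was called lower (median -0.17, camera adjusted p = 2.64e-04), and lost its call with an estimated correlation (adjusted p = 0.573). Tet2, which oxidizes 5-methylcytosine, fell from 5186 ± 455 to 3365 ± 135 (-0.62 ± 0.084, adjusted p = 0.00423), with Tet1 at -0.77 ± 0.27 and Tet3 at -0.49 ± 0.17. Tet2 was the single called gene of the 13 in the DNA methylation list. Besides enzymes that remove the mark, this list holds methyltransferases such as Dnmt1 and binding proteins such as Mbd2. That list was called lower (median -0.096, adjusted p = 0.0339; adjusted p = 0.573 with an estimated correlation), but not without young library 1 (adjusted p = 0.0634), young library 3 (0.067) or old library 1 (0.078), nor with the fibroblast marker covariate (0.0763). Its median was then -0.078, -0.038, -0.11 and -0.12. Its adjusted p was 0.0664 with eBayes without the trend and 0.0579 without young library 3 and old library 3 (median -0.047). In the Polycomb group 1 of 28 genes was called, Cbx7, which rose (0.53 ± 0.11, adjusted p = 0.0227). Of 19 replication-dependent histone genes 2 rose, H4c8 and H3c7, from low levels (98.8 and 78.1 in old) and with near-identical copies elsewhere in the genome, with H2bc3 (2.47 ± 0.73) a further gene over the list alone. Neither list was called (adjusted p = 0.792 and 0.726), and none of 24 Hox cluster genes passed limma (1 at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2, list adjusted p = 0.649). The medians of the Polycomb, histone and Hox lists were 0.034, 0.11 and 0.071, and under quantile normalization -0.032, -0.0095 and -0.093. The Polycomb median was -0.0017 with edgeR and -0.0099 with DESeq2.

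Imprinted genes moved both ways. Of 26 tested, 4 fell and 3 rose, and 4 were higher and 6 lower adjusted over the list alone. The maternally expressed non-coding RNA Meg3 fell from 13199 ± 2512 to 5009 ± 882 (-1.39 ± 0.16, adjusted p = 0.0021). Mirg of the same cluster fell too (-0.97 ± 0.23) and was named, like Grb10 (-0.47 ± 0.12) and Sgce (0.45 ± 0.094), after its value was seen. Mest fell (-1.24 ± 0.19, adjusted p = 0.00656), while Igf2 rose from a low level, 71.0 ± 6.83 to 146 ± 7.9 (1.03 ± 0.17, adjusted p = 0.00958), and Dcn, also a fibroblast marker, rose. The list was not called (median -0.12, adjusted p = 0.115).

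The markers that define the sorted cells were present at both ages. Pax7 had 2441 ± 419 normalized counts in young and 2749 ± 493 in old, Myf5 3487 ± 545 and 3179 ± 269.9, Myod1 16087 ± 2593 and 15731 ± 4568, and Vcam1, used to sort such cells in many protocols, 16131 ± 2482 and 20374 ± 2636. None of these passed the test (log2 fold changes 0.17, -0.12, -0.064 and 0.34). Of 31 tested identity genes, 4 fell and none rose. They were the laminin receptor subunit Itga7 (-0.68 ± 0.11, adjusted p = 0.00954), Chrdl2, a BMP antagonist (-0.76 ± 0.17, adjusted p = 0.0298), the calcitonin receptor Calcr, which maintains quiescence (-0.47 ± 0.082, adjusted p = 0.0114), and the endothelin gene Edn3 (-0.48 ± 0.080, adjusted p = 0.00941). Adjusted over the list alone 5 were lower and 1 higher, with Hey1 at -0.54 and Sdc2, named after its value was seen, at 0.38. The list was called lower (median -0.12, camera adjusted p = 0.0223), but not with an estimated correlation (adjusted p = 0.573). It also lost the call under quantile normalization (adjusted p = 0.196) and without young library 1 (0.0772) or young library 4 (0.0519). Its median was then -0.11, -0.096 and -0.11. With the fibroblast marker covariate it kept the call (adjusted p = 0.0286, median -0.17).

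Quiescence-associated genes split, with 2 of 38 higher and 2 lower. Ddx6, an RNA helicase of processing bodies (0.45 ± 0.089), and Bmp4 (0.49 ± 0.11) rose, while Calcr and the collagen gene Col5a1 (-0.81 ± 0.12, adjusted p = 0.00645) fell. Of the list, 3 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.13). Of 24 genes of activation and myoblast commitment, Eif4ebp1, the translation repressor, fell (-0.66 ± 0.13, adjusted p = 0.0165), also over the list alone, and the cyclin Ccnd1 had -0.99 ± 0.31 (adjusted p = 0.0936). That list was called lower (median -0.13, adjusted p = 0.012; adjusted p = 0.666 with an estimated correlation), and lost its call under quantile normalization (adjusted p = 0.0757), without young library 4 (0.0594) or old library 4 (0.0957), and with the fibroblast marker covariate (0.263). Its median was then -0.13, -0.061, -0.089 and -0.15. Of 21 differentiation genes, Chrna1, the acetylcholine receptor subunit (2173 ± 291 to 1138 ± 109.9, -0.93 ± 0.12, adjusted p = 0.00274), and Tnnt1 (-0.66 ± 0.14) fell. Of these genes 5 were lower over the list alone, and the list was not called (median 0.030, mean -0.099, adjusted p = 0.132, test statistic pointing down).

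Few genes of the cell cycle passed the test. Among 45 cell cycle genes only Rrm2, a ribonucleotide reductase subunit, was called (0.62 ± 0.14, adjusted p = 0.031). The list pointed the other way, with 28 of 45 genes below 0 (median -0.15, mean -0.21), and was not called (camera adjusted p = 0.0788). Cdkn1a, an inhibitor of the cell cycle, fell from 18233 ± 2384 to 11248 ± 2169 (-0.71 ± 0.15, adjusted p = 0.0244), a call lost in 5 of 23 alternatives. It had a within-age correlation of -0.655 with the level of fibro-adipogenic progenitor markers, and with the fibroblast marker covariate it was at -0.36 (adjusted p = 0.613). Cdkn1a belonged to a list of 20 cell cycle inhibitors and senescence genes, of which 1 rose and 1 fell. Over the list alone 2 were higher and 1 lower, with Bhlhe40 (0.55 ± 0.16) the further gene (list adjusted p = 0.569). Of 30 p53 targets, Perp rose (2.16 ± 0.24, adjusted p = 0.0017) and Cdkn1a, Sesn2 and Ccng2 (-0.57 ± 0.13) fell. Of this list 3 were higher and 4 lower over the list alone, and the list was not called (median 0.028, mean 0.069, adjusted p = 0.632, test statistic pointing down). The median of the p53 list was -0.020 under quantile normalization, -0.016 with edgeR and -0.024 with DESeq2.

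Several endoplasmic reticulum chaperones fell in old cells. Of 33 genes of the unfolded protein and integrated stress response, 11 fell and none rose, and 23 passed adjusted over the list alone (22 lower and 1 higher). Hspa5, the main chaperone of the endoplasmic reticulum and the most abundant transcript in 2 of the young libraries, fell from 217347 ± 5188 to 153112 ± 19862 (-0.51 ± 0.12, adjusted p = 0.0405), a call that it lost in 15 of 23 alternatives. Hsp90b1, another chaperone of that compartment, fell from 22182 ± 558 to 15467 ± 795 (-0.52 ± 0.076, adjusted p = 0.00562). The co-chaperone Dnajc3 (-0.49 ± 0.088), the disulfide isomerase Pdia6 (-0.43 ± 0.080) and the stress sensor Sesn2 (-0.61 ± 0.11) fell with adjusted p of 0.0132, 0.0152 and 0.0133. With the fibroblast marker covariate the median of the list was -0.28 against -0.36. The regulators Atf4, Ddit3 and Xbp1, named after their values were seen, did not pass (-0.013 ± 0.087, 0.023 ± 0.12 and -0.12 ± 0.099). The list was called lower (median -0.36, camera adjusted p = 1.41e-12), and not with an estimated correlation (adjusted p = 0.469). Its mean log2 level separated all 4 old from all 4 young libraries (difference -0.33, exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 allows).

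Other stress genes went both ways. Of 21 heat shock genes, Hspa5 and Hsp90b1 fell and Hspb8, a small heat shock protein, rose from 385 ± 81.0 to 874 ± 105 (1.20 ± 0.16, adjusted p = 0.00378). Hspb8 had a within-age correlation of 0.813 with the level of fibro-adipogenic progenitor markers. Of the heat shock genes 2 were higher and 3 lower over the list alone (list adjusted p = 0.854). Of 32 immediate early genes, which respond to tissue dissociation among other stimuli, Ccn2 (1.20 ± 0.14, adjusted p = 0.00222) and Ier3 (0.52 ± 0.13) rose and Nr4a3 (-0.98 ± 0.14, adjusted p = 0.00494) and Egr3 (-0.69 ± 0.12) fell. There were 5 higher and 2 lower over the list alone (median 0.10, list adjusted p = 0.424). Ribosomal protein genes were called lower as a list (median -0.15, camera adjusted p = 7.58e-08), but a single gene of 79, Rpl37a, passed over all genes (-0.48 ± 0.12, adjusted p = 0.0492) and none over the list alone. With an estimated correlation the adjusted p of that list was 0.803, and with the fibroblast marker covariate 0.0994 (median -0.037). Many such genes have processed pseudogenes that can share their reads. None of 35 proteasome genes passed limma, over all genes or over the list alone (1 at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2, median -0.049, list adjusted p = 0.0788).

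**Figure D2:**
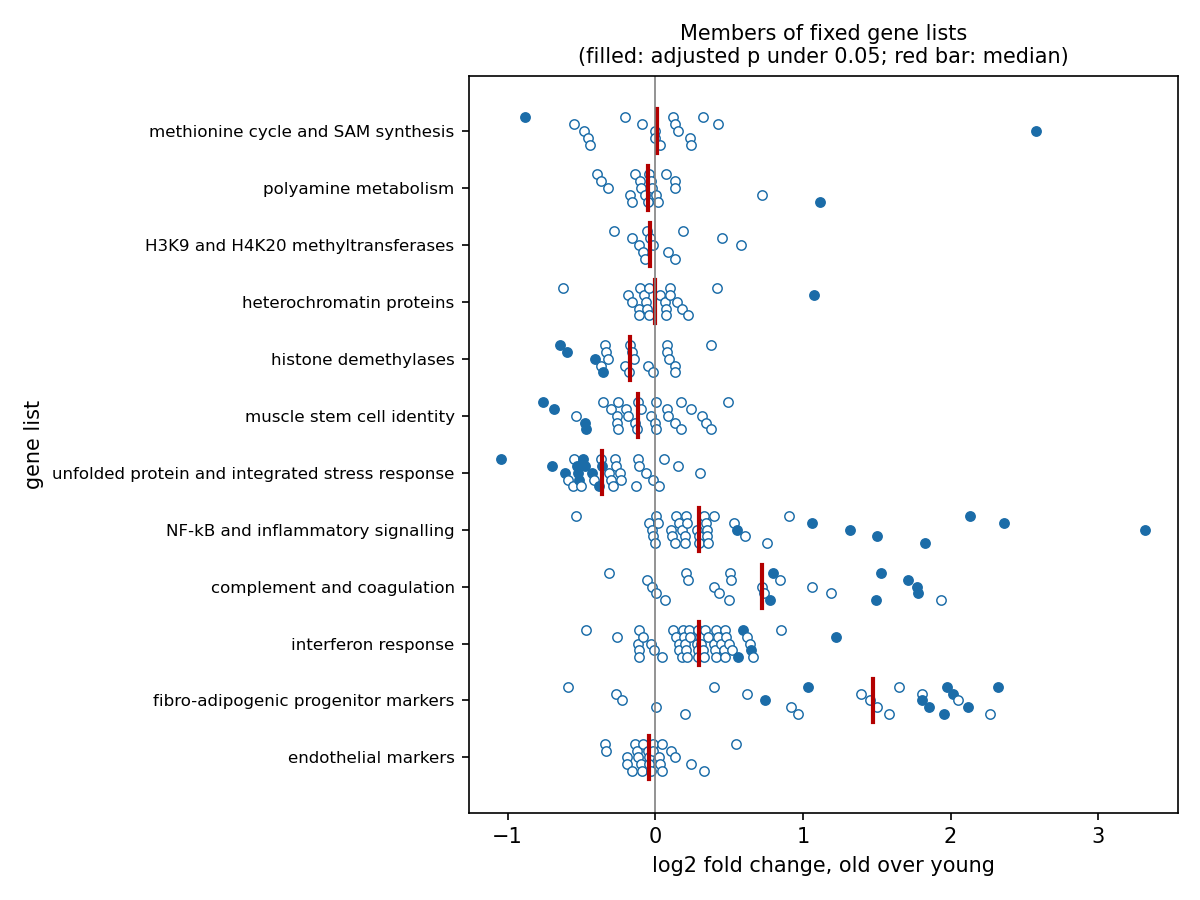
Log2 fold change (old over young, x axis) of every tested member of 12 fixed gene lists (1 point per gene, filled where the adjusted p over all genes was under 0.05, vertical bar at the list's median). The stress response list had its median at -0.36 with 11 filled points left of 0, and the fibro-adipogenic progenitor list its median at 1.48 with 9 filled points right of 0.

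Several inflammatory genes rose in old cells. Of 38 genes of NF-kB and inflammatory signalling, 8 rose and none fell, and 13 were higher and 1 lower adjusted over the list alone. Il33, an alarmin cytokine (239 ± 71.6 to 1202 ± 242, 2.36 ± 0.23, adjusted p = 7.68e-04), Il6 (2239.8 ± 537 to 4648 ± 1071, 1.06 ± 0.19, adjusted p = 0.0136), the prostaglandin E synthase Ptges (2.13 ± 0.39) and the chemokine Ccl7 (1.5 ± 0.24) were among them. Of 35 secretory factors tied to senescence, 7 rose and none fell (15 higher and 2 lower adjusted over the list alone). Among them were the eotaxin Ccl11 (1056 ± 284 to 6088 ± 1475, 2.54 ± 0.21, adjusted p = 5.62e-04) and Timp1, an inhibitor of matrix proteases (1.01 ± 0.16, adjusted p = 0.00662). Of 25 complement and coagulation genes, 7 rose and none fell (10 higher adjusted over the list alone), with C4b (1.78 ± 0.32) and C1s1 (1.5 ± 0.27) among them. Camera called these 3 lists higher (medians 0.30, 0.58 and 0.72, adjusted p = 6.44e-06, 4.73e-05 and 3.65e-05). With an estimated correlation the adjusted p was 0.573 for each. The mean log2 level of fibroblast and tenocyte markers differed by 1.35 between the ages (exact permutation p = 0.0571). With it as a covariate the camera adjusted p of the 3 lists was 0.248, 0.085 and 0.515 and their medians 0.13, 0.30 and 0.21. The median SE of their genes went from 0.16 to 0.27, from 0.32 to 0.50 and from 0.34 to 0.44. Age accounts for 62.8% of the variance of that level, so the lost calls cannot tell fibroblast content from age.

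Of 52 interferon response genes, 4 rose and none fell, the same number over the list alone. They were the nucleic acid sensors Zbp1 (193 ± 47.2 to 452 ± 104, 1.23 ± 0.22, adjusted p = 0.0138) and Ddx58 (0.59 ± 0.11), the oligoadenylate synthetase-like gene Oasl2 (0.65 ± 0.13) and the transcription factor Irf7 (0.56 ± 0.13). The list was called higher (median 0.30, adjusted p = 1.48e-04), but not with an estimated correlation (adjusted p = 0.727). Its mean log2 level did not pass (exact permutation p = 0.143), and young library 3 (10.19) lay above the old libraries (10.04 to 10.10). None of 22 antigen presentation genes passed limma over all genes or over the list alone (4 were higher at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2). Nor did their mean log2 level pass (exact permutation p = 0.343). Yet the list was called higher (median 0.32, adjusted p = 0.033), though not with an estimated correlation (adjusted p = 0.811). It lost that call without young library 1 (0.269), young library 4 (0.113) or old library 4 (0.126), with eBayes without the trend (0.0529), edgeR (0.0593; with the replicate block 0.0726) and DESeq2 (0.0652), and with the fibroblast marker covariate (0.248). Its median was 0.14, 0.21 and 0.18 without these libraries, 0.24 with edgeR, 0.23 with DESeq2 and 0.20 with the covariate. The genes nearest to a call were Nlrc5 (0.54 ± 0.17) and Tapbp (0.34 ± 0.12). In JAK-STAT signalling 2 of 23 genes rose, the oncostatin M receptor Osmr (10272 ± 1541 to 15435 ± 2051, 0.59 ± 0.13) and the feedback inhibitor Cish (0.44 ± 0.096), with Socs3 a further gene over the list alone (0.57 ± 0.15; list adjusted p = 0.38).

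Several markers of connective tissue cells, which are not the target of the sort, were higher in the old libraries. Of 26 markers of fibro-adipogenic progenitors, the fibroblast-like cells of muscle, 9 rose and none fell, and 18 were higher and 1 lower adjusted over the list alone. The proteoglycans Dcn and Lum rose from 9428 ± 4449.6 to 48864 ± 23598 (2.32 ± 0.39, adjusted p = 0.0104) and from 863 ± 389 to 3711 ± 1395 (2.12 ± 0.33, adjusted p = 0.00691). Cxcl14 (2.02 ± 0.34) and Hic1 (1.03 ± 0.16) rose too. Pdgfra, the receptor that marks these cells, had 1.80 ± 0.52 (adjusted p = 0.0769) and Ly6a 0.20 ± 0.45 (adjusted p = 0.857). Of 14 tenocyte markers, 5 rose and none fell (9 higher over the list alone). They were Thbs4 (1780.2 ± 543 to 18233 ± 14380.4, 3.05 ± 0.51, adjusted p = 0.00961), the tendon membrane protein Tnmd (2.46 ± 0.52), the transcription factor Mkx (1.22 ± 0.27), Comp (2.56 ± 0.57) and Fmod (2.79 ± 0.63), the last named after its value was seen. Both lists were called higher (medians 1.48 and 1.73, camera adjusted p = 1.04e-07 and 5.08e-06), and neither with an estimated correlation (adjusted p = 0.573 and 0.586). The mean log2 level of the 40 markers of both lists was 1.35 higher in old (exact permutation p = 0.0571, two-sided) and ran from 10.3 in old library 3 to 11.9 in old library 2, against 9.43 to 10.6 in young. The abundant fibroblast gene Col3a1, named after its value was seen, was lower in old over the list alone, 30631 ± 6418 to 20689 ± 6378 (-0.59 ± 0.22, adjusted p over all genes = 0.152).

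Endothelial markers did not pass the test, and macrophage markers were called higher as a list. None of 26 endothelial markers passed limma over all genes or over the list alone, at an unadjusted p under 0.05, or with edgeR or DESeq2. Pecam1 was at 5439 ± 3406 in young and 5025 ± 2806 in old (-0.044 ± 0.43) and Cdh5 at -0.34 ± 0.45 (median -0.044, list adjusted p = 0.535). Their level varied within each age, with mean log2 levels of 12.2 in young library 3 and 11.9 in old library 3 against 10.3 to 11.2 in the other libraries. With the endothelial level as a covariate, chosen after the data were seen, 890 genes were higher and 482 lower, and without these 2 libraries 533 and 285. Of 22 macrophage markers, Cd14 rose (0.89 ± 0.18, adjusted p = 0.0225) and Ccr2 joined it over the list alone from a low level (4.37 to 27.3), while the leukocyte antigen Ptprc did not pass (75.5 ± 61.2 and 111 ± 81.2). The within-age correlations of Cd14 and Ccr2 with the level of fibro-adipogenic progenitor markers were 0.824 and 0.745. With the fibroblast marker covariate Cd14 was at 0.40 (adjusted p = 0.616), and it lost its call in 7 of 23 alternatives. The macrophage list was called higher (median 0.84, adjusted p = 0.00269; adjusted p = 0.803 with an estimated correlation), and not without old library 4 (adjusted p = 0.0722, median 0.47) or with the fibroblast marker covariate (adjusted p = 0.655, median -0.018).

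Other marker lists held few called genes. Of 20 pericyte and smooth muscle markers Aspn (1.90 ± 0.35) and Abcc9 (1.02 ± 0.22) rose. Of 20 Schwann cell markers Scn7a rose (2.00 ± 0.23, adjusted p = 0.00191). The within-age correlations of Aspn, Abcc9 and Scn7a with the level of fibro-adipogenic progenitor markers were 0.755, 0.574 and 0.643. Of 7 T and NK cell markers Thy1 fell (-1.17 ± 0.21, adjusted p = 0.0138). Of 32 mature fibre transcripts Actn3 (6487 ± 897 to 3083 ± 615, -1.08 ± 0.14, adjusted p = 0.00382) and Tnnt1 fell, with the same counts over each list alone. The mature fibre list itself pointed the other way, with 26 of 32 genes above 0 (median 0.29, mean 0.17). None of the markers of neutrophils (10 tested), B cells (15), erythroid cells (9) or adipocytes (12) passed limma over all genes. At an unadjusted p under 0.05 there were 1, 0, 0 and 1, with edgeR 0 in each list and with DESeq2 1, 0, 0 and 0, and the neutrophil gene G0s2 was higher over its list alone (0.53 ± 0.15). None of these 8 lists was called (adjusted p between 0.130 and 0.974). The neutrophil list had a median of -0.27 with the test statistic pointing up. The T and NK cell list had a median of 0.13 with the statistic pointing down, and -0.18 under quantile normalization. The adipocyte list had a median of -0.033 and a mean of 0.069.

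**Figure D3:**
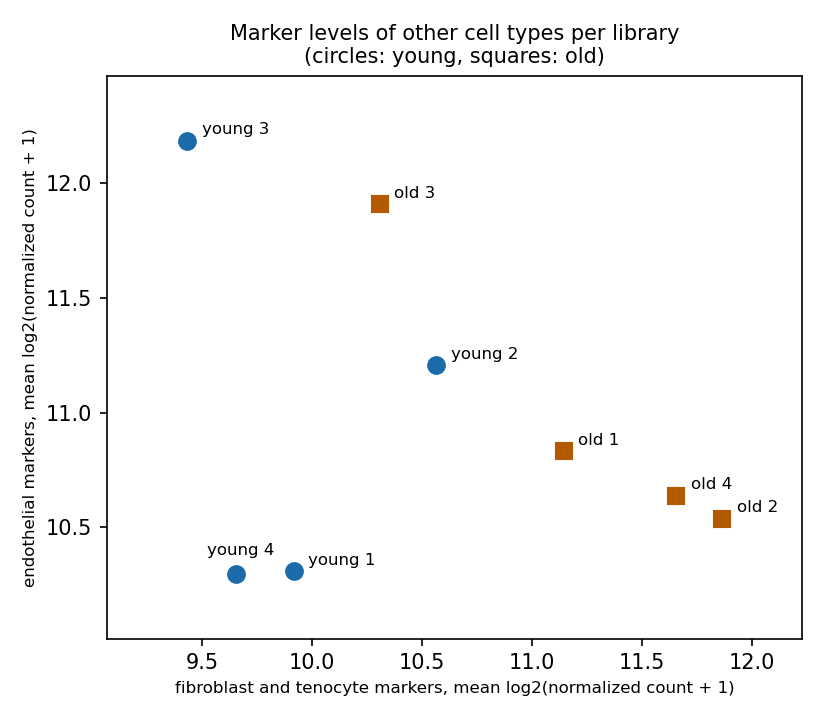
Mean log2 level (log2(normalized count + 1)) of the 40 fibroblast and tenocyte markers (x axis) against that of the 26 endothelial markers (y axis), 1 point per library. The old libraries lay at 10.3 to 11.9 on the x axis and the young at 9.43 to 10.6, and young library 3 and old library 3 stood highest on the y axis at 12.2 and 11.9.

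Extracellular matrix genes changed in both directions. Of 50 tested, 10 rose and 4 fell, and 17 were higher and 8 lower adjusted over the list alone. Col4a5, Col8a1 (572 ± 216 to 1978 ± 513, 1.83 ± 0.26, adjusted p = 0.0052) and the proteoglycan Ogn (1.60 ± 0.24, adjusted p = 0.00596) rose. Col5a1 fell (8778 ± 1157 to 5012 ± 707), and Col4a1 (-0.65 ± 0.14), Lamc1 (-0.49 ± 0.094) and Sparc (-0.73 ± 0.14), named after their values were seen, fell too. The list was not called (median 0.44, adjusted p = 0.0788). Dcn and Lum, which are also fibroblast markers, were among the genes that rose, and the fibroblast marker level was 1.35 higher in old (exact permutation p = 0.0571).

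The TGF-beta, Wnt, Notch and FGF lists were not called. In the TGF-beta and BMP list 7 of 47 genes rose, Inhba (1.68 ± 0.32) and Bmp6 (4817 ± 844 to 7868 ± 1142, 0.71 ± 0.14) among them. Of the list 2 fell, the procollagen protease Bmp1 (-0.82 ± 0.12, adjusted p = 0.00562) and Smad5 (-0.39 ± 0.086, named after its value was seen). There were 10 higher and 3 lower over the list alone (adjusted p of the list = 0.142). Of 38 Wnt genes, Wls, which carries Wnt proteins to the cell surface (0.61 ± 0.084, adjusted p = 0.0046), and the secreted antagonist Sfrp4 (289 ± 169 to 1196 ± 391, 2.14 ± 0.34, adjusted p = 0.00729) rose. Of the list 9 were higher and 3 lower over the list alone (list adjusted p = 0.107). In the Notch list the gamma-secretase subunit Psen2 (620.0 ± 12.3 to 342 ± 45.7, -0.86 ± 0.12, adjusted p = 0.00474) and the coactivator Maml1 (-0.59 ± 0.12) fell, also over the list alone, out of 33 genes (median -0.10, list adjusted p = 0.0988). Fgf7 rose (1.79 ± 0.41, adjusted p = 0.0333) among 33 FGF and MAPK genes, also over the list alone (median -0.043, mean 0.078, list adjusted p = 0.237, test statistic pointing down). Inhba, Fgf7, Sfrp4 and Wls had within-age correlations with the level of fibro-adipogenic progenitor markers of 0.889, 0.761, 0.656 and 0.59. With the fibroblast marker covariate they were at 0.58, 0.83, 1.51 and 0.49 and did not pass.

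Metabolic genes changed in a few places. Of 24 glycolysis genes, the lactate transporters Slc16a3 (3834 ± 295 to 6279 ± 1188, 0.70 ± 0.13, adjusted p = 0.0136) and Slc16a1 (0.55 ± 0.12), the enzyme Tpi1 (0.54 ± 0.12) and Gpi1 (0.37 ± 0.084, named after its value was seen) rose. The phosphofructokinase Pfkp fell (-0.47 ± 0.089, adjusted p = 0.0152), with 7 higher and 3 lower over the list alone (list adjusted p = 0.329). Of 35 glutathione and NRF2 target genes, 4 rose and none fell. They were the glutathione transferases Gstm2 (1134 ± 80.8 to 1968 ± 123, 0.80 ± 0.089, adjusted p = 0.00165) and Gstt1 (0.45 ± 0.10), the extracellular superoxide dismutase Sod3 (0.62 ± 0.14) and G6pdx (0.47 ± 0.11). Gstm1, a close paralogue named after its value was seen, was a further gene over the list alone (0.40 ± 0.10). That list was called higher (median 0.13, adjusted p = 0.0223; adjusted p = 0.573 with an estimated correlation), and not without young library 2 (0.0555) or old library 1 (0.104), nor with edgeR (0.0503; with the replicate block 0.0533). Its median was 0.14, 0.095, 0.082 and 0.096 in these settings.

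In other metabolic groups few or no genes passed the test. Of 40 autophagy and lysosome genes 1 rose and 2 fell, the latter Ulk1, a kinase that starts autophagy (-0.65 ± 0.11, adjusted p = 0.00981), and Wipi2 (-0.49 ± 0.088), with 3 higher and 2 lower over the list alone (list adjusted p = 0.691). None of 74 nuclear-encoded respiratory chain genes or 28 fatty acid oxidation genes passed limma, over all genes or over the list alone. In each list 5 passed at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2 (list medians -0.040 and 0.047, adjusted p = 0.0601 and 0.974), and with DESeq2 the fatty acid oxidation median was -0.0037. The 13 mitochondrially encoded genes were listed at 0 in all 8 libraries. The Y-linked genes Ddx3y (-0.11 ± 0.13), Uty (-0.25 ± 0.12), Eif2s3y (0.064 ± 0.19) and Kdm5d (0.022 ± 0.24) were expressed in both ages and none passed.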

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

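The tests of a lower share of muscle stem cells, of dilution and of a weaker dissociation response were chosen only after the result was seen. Among 434 groups of 4 libraries examined, 29 held a library far from the others of its age, where chance gives about 1 in 20. Old library 1 lay below the other old libraries in the normalized counts of Tmpo by a small distance (2489 against 2656 to 2674). Old library 1 lay far above the other old libraries in the normalized counts of Srm (1761). Old library 2 lay far above the other old libraries in the normalized counts of Abcc9 (1429), C4b (4436), Col4a5 (719.9), Edil3 (410.2), Mbd1 (3489), Mmp3 (2313) and Sv2b (1312). Old library 3 lay far above the other old libraries in the normalized counts of Cdh5 (3053) and Pecam1 (9212). Old library 4 lay far below the other old libraries in the normalized counts of Bicd1 (283), Ccng2 (1213), Ddx6 (4393), Pfkp (6240.1), Psat1 (246) and Tnfrsf21 (1638). Old library 4 lay far above the other old libraries in the normalized counts of Col5a1 (6066) and Pax7 (3485). Young library 1 lay far below the other young libraries in the normalized counts of Actb (30885). Young library 1 lay far above the other young libraries in the normalized counts of Rrm2 (2364). Young library 2 lay far above the other young libraries in the normalized counts of Inmt (510.0) and Sfrp4 (540.4). Young library 3 lay far below the other young libraries in the normalized counts of Slc16a3 (3397). Young library 3 lay far above the other young libraries in the normalized counts of Bicd1 (106), Ehmt2 (1356) and Smox (1112). Young library 4 lay far above the other young libraries in the normalized counts of Kdm1a (3324) and Spock1 (52.9).

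Other splits of the 8 libraries bear on the counts. The 773 called genes and the 306 called genes that differed at least 2-fold were matched by 1 of the 35 splits, the real one, with at most 5 in any other. That goes against chance only as far as 35 splits allow (exact permutation p = 0.0286 for each count, the smallest possible). Every other split mixed young and old libraries, so its count is not free of a difference by age. For the 15 called lists chance cannot be excluded, since 14 splits gave as many and the highest other gave 23. Exact permutation tests of their mean log2 levels gave p = 0.0571 for histone demethylases, complement and coagulation, fibro-adipogenic progenitor and tenocyte markers. The p was 0.143 for the DNA methylation and interferon lists and 0.171 for ribosomal proteins and macrophage markers. It was 0.257 for activation, 0.343 for antigen presentation and 0.0286 for the other called lists.

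Camera called the markers of fibro-adipogenic progenitors and tenocytes higher in old libraries, but not with an estimated correlation (adjusted p = 0.573 and 0.586), and their mean log2 level, 1.35 higher, did not pass (exact permutation p = 0.0571). A candidate explanation is more fibroblast-like cells in the old sorts. With the mean of each age subtracted, the 40 markers varied together (mean pairwise correlation 0.485, against at most 0.0842 in 1000 random lists). That shows markers varying jointly between libraries, and not that such cells were more frequent in old. Endothelial markers varied together too (estimated correlation 0.957), and their level did not differ by age (exact permutation p = 0.943). Over the list alone 18 progenitor markers were higher and 1, Col3a1, lower, though Col3a1 also followed the progenitor level within age (0.833). All 40 also had a mean of at least 10 in young libraries, and 11 were held by other lists. A lower share of muscle stem cells would raise endothelial markers alike, and the difference of the fibro-adipogenic progenitor and endothelial lists, 1.23 (exact permutation p = 0.2), leaves that open. For the genes at least 2-fold higher outside that list (median within-age correlation with the fibro-adipogenic progenitor level 0.496, 126 of 252 above 0.5 and 54 below 0, against a median of -0.0060 and 15.9% above 0.5 over all tested genes), more such cells and an untested change with age in either cell type cannot be told apart, as age accounts for 62.8% of the variance of the marker level.

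Camera called the stress response list lower in old (median -0.36), but not with an estimated correlation (adjusted p = 0.469). The list fell further than the identity list (difference -0.23, exact permutation p = 0.0286, the smallest possible), which goes against an equal dilution of both. Dilution of muscle stem cells by other cells stays undecided, since identity genes need not be absent from other cells. Over the identity list alone 5 genes were lower and Sdc2 higher, and Sdc2 had a within-age correlation of 0.528 with the fibro-adipogenic progenitor level. That value did not hold in young, where library 2 had the highest progenitor level (10.9) and the lowest Sdc2 count (2418). Of the stress genes, Pdia6 and Dnajc3 correlated with that level by -0.740 and -0.621, Hspa5 by -0.225 and Phgdh by 0.782. A trend with GC content or gene length is argued against, since the median was -0.50 after it was subtracted. A weaker dissociation response could not be decided, the immediate early list differing by 0.12 (exact permutation p = 0.229). A difference of age within the cells stays open, as an untested hypothesis.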

How the results depend on the processing

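The covariates of fibroblast and endothelial markers and the run without young library 3 and old library 3 were chosen only after the result was seen. Where a value moved, the cause was not tested, except that fewer libraries give less power. Genes higher and lower in old (495 and 278) were 268 and 134 with eBayes without the trend, 768 and 601 with DESeq2, 7 and 3 with the fibroblast covariate and 890 and 482 with the endothelial covariate. They were 213 to 523 and 117 to 316 when 1 library was left out. At least 2-fold, 260 and 46 became 7 and 2 with the fibroblast covariate, lower genes were 81 under quantile normalization and 76 with DESeq2, and higher genes were 130 to 317 when 1 library was left out. Lists higher and lower (9 and 6) were 0 and 0 with an estimated correlation and 2 and 2 with fry, and lists higher were 14 under quantile normalization and 3 with the fibroblast covariate. The SAM median was -0.10 under quantile normalization. The polyamine median was -0.12 with the fibroblast covariate, 0.025 without young library 3 and old library 3 and -0.087 to 0.020 when 1 library was left out. The heterochromatin protein median was -0.083 under quantile normalization, -0.047 with DESeq2 and 0.072 with the fibroblast covariate. Of 142 called genes named in the text, 8 passed in the same direction under every alternative, the fibroblast covariate included. With the replicate number as a block, 559 genes were higher and 252 lower. The labels do not pair the libraries by number. The deviations of same-numbered young and old libraries correlated by 0.19, 0.072, 0.30 and -0.042, and 5 of 8 libraries, not all, correlated best with their own number, a hint from the data that leaves pairing open. At this depth 1 read was worth 0.60 to 1.07 normalized counts, which limits values near the minimum mean of 10.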

Other observations

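The aminoacyl-tRNA synthetase and cholesterol lists, their tests and the single genes in this part were chosen only after some of their values were seen. Of 20 tested cytosolic aminoacyl-tRNA synthetases, the enzymes that charge transfer RNAs, 6 fell in old cells and none rose. Among them were Nars (-0.54 ± 0.11, adjusted p = 0.0215), Yars (-0.52 ± 0.097, adjusted p = 0.0146) and Lars (-0.51 ± 0.092, adjusted p = 0.0132). Of the 14 that were not called, 11 had a log2 fold change below 0 (median -0.21), and their mean log2 level did not pass (exact permutation p = 0.0571). Of 20 tested genes of cholesterol synthesis, 5 fell and none rose. Among them were the sterol demethylase Cyp51 (-0.55 ± 0.10, adjusted p = 0.0138), Msmo1 (-0.68 ± 0.11, adjusted p = 0.00731) and the early enzyme Hmgcs1 (-0.44 ± 0.078, adjusted p = 0.0124). Of the 15 that were not called, 13 lay below 0 (median -0.18, exact permutation p = 0.0571). Over all 20 genes of each family, 17 synthetases and 18 cholesterol genes lay below 0. The mean log2 levels differed by -0.26 and -0.27 (exact permutation p = 0.0286 each, the smallest possible). The called members had been seen before the lists were written, and leaving them out keeps only genes that did not pass. A fall of either family as a whole was therefore neither shown nor excluded.

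Actb, the cytoskeletal actin gene that is often used as a reference for normalization, rose from 36098 ± 3479 to 114964 ± 10377 normalized counts (1.67 ± 0.11, adjusted p = 1.66e-04), with all old libraries above all young ones. The related Actg1 did not pass, at 40654 ± 4852 and 40770.0 ± 6648 (-0.0017 ± 0.13). Gpnmb, a lysosomal glycoprotein, rose from 251 ± 61.5 to 2204 ± 924 (3.05 ± 0.30, adjusted p = 8.28e-04). Eya2, a transcriptional coactivator in muscle progenitors, rose from 175 ± 43.7 to 900.0 ± 175 (2.36 ± 0.21), and Bicd1, an adaptor of dynein, from 73.0 ± 21.9 to 381 ± 65.4 (2.39 ± 0.22). These 4 genes were also among the 10 that passed with the fibroblast marker covariate, at 1.69, 1.91, 1.70 and 2.78 in the order Actb, Gpnmb, Eya2 and Bicd1. Their within-age correlations with the level of fibro-adipogenic progenitor markers were -0.0333, 0.926, 0.879 and -0.565 in that order.

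Genes of the circadian clock differed between the ages: Arntl fell from 2749 ± 186 to 1144 ± 151 (-1.27 ± 0.11, adjusted p = 5.62e-04) and Npas2 fell (-1.08 ± 0.24), while Per3 (0.63 ± 0.14), Nr1d2 (0.56 ± 0.13), Dbp (1.12 ± 0.21) and Tef (0.60 ± 0.10) rose. Per1 was at -0.013 and Nr1d1 at -0.12. A candidate explanation is another time of day at isolation of the old cells, since the 10 genes in antiphase to Arntl had a median of 0.58 and the 6 in phase a median of -0.40 (difference of mean log2 levels 0.91, exact permutation p = 0.0286). Of these 16 genes Arntl alone had been seen when the lists were written, and without it the 5 in phase had a median of -0.31 and the difference was 0.75 (exact permutation p = 0.0286, the smallest possible). The labels give no time of isolation, and a change of the clock with age stays open as well.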
